A study of Mus musculus with 6 samples.

How the data were processed

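Gene expression was measured in CD11b-selected cells from mouse brain, in 3 libraries from control mice (CT) and 3 from mice with the conditional genotype (Rac1 cKO). Per the labels' protocols, 1 ng of RNA per library was amplified over 16 cycles with the AmpliSeq mouse transcriptome kit and sequenced on an Ion S5XL instrument. Per the file headers, the deposited values were made with ampliSeqRNA 5.12.0.1 and RPM-normalized quantification 1.0, and each is a log2 of RPM + 1. The aligner and the genome build were not given in the sources used here, and no coordinates were used. Each file listed 23930 symbols, of which 22305 matched a symbol in the reference tables. The groups were taken from the genotype labels.

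Read counts were recovered by undoing the logarithm and dividing by the value of 1 read in each library. Between 99.992% and 99.996% of the values came out whole to within 0.1 read. The recovered totals, given per library in the report, ran from 14336964 to 20509250, so that 1 read was worth 0.0488 to 0.0697 RPM. The counting error of the reads is therefore small for the genes tested. How many RNA molecules were captured from 1 ng before amplification was not measured. The spread between the 3 libraries of a group limits the precision. Fold changes are differences on the log2(RPM + 1) scale, with a pseudocount of 1, and understate changes of genes with low values. Pearson correlations between libraries over the tested genes ran from 0.905 (CT 1 with Rac1 cKO 3) to 0.982 (Rac1 cKO 1 with Rac1 cKO 2), and no 2 libraries were duplicates.

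Genes with a mean of at least log2(5 + 1) over the 6 libraries were tested, which kept 10006 genes. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend, 2-sided), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors are the moderated ones and intervals are 95% intervals. The design written before the data were examined had the genotype as its only term. The barcodes fell into 2 separate runs of numbers with 3 libraries each, so a fit with this barcode set as a block was planned beside it as an alternative. The set was read from an identifier in the file headers, which splits the libraries in the same way as the barcodes. The values within each set were added after the data were seen. Set 1 compares 2 Rac1 cKO libraries with 1 CT library and set 2 compares 1 with 2, and no test was made within a set. A test of the difference between the sets' genotype effects called 1 gene (156 at an unadjusted p under 0.05).

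Groups of genes were tested with limma's camera (preset correlation between genes of 0.01), adjusted over the 26 of 30 fixed lists with at least 5 tested members, and again with an estimated correlation and with fry. The lists were fixed before the data were examined. They cover regulators and effectors of Rac, actin, NADPH oxidase, adhesion, microglial states, complement, lysosome, cytokines, interferon response, antigen presentation, growth factors, immediate early genes, metabolism, ribosomal proteins, the cell cycle and markers of cell types. Members that were not listed by symbol were left out, and 26 genes belong to more than 1 list. Members were also adjusted over the list alone.

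The genes named were chosen by a rule fixed in advance. It takes Cx3cr1, and among genes past the threshold with non-overlapping groups the 10 with the highest and the 10 with the lowest log2 difference. Where fewer passed, the genes of that direction with the smallest unadjusted p and non-overlapping groups fill the places, and of each list the 2 members with the smallest p and up to 2 of the most abundant are named. The rule was applied to the fit without the set and, after the data were seen, to the fit with it. The list members Abca1, Csf3r, Ctsz, Cx3cl1, H2-D1, H2-Q4, Mcm3 and Mertk, and the genes named in the closing section beyond those of the report, were chosen after their values were seen. Rac1 itself was not analysed here, and 1 of the tested lists and some single genes that the rule takes are not reported here.

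Alternatives planned before the data were examined were no filter, a stricter filter of 20 RPM (6671 genes), quantile normalization, median centring, a pseudocount of 5, no variance trend, robust variance, array quality weights, voom on recovered reads, an equal-variance test per gene, other thresholds, a replicate block, the barcode set as a block, lists without shared genes or without the genotype genes, and leaving out each library in turn. A loess correction of each library for GC content and transcript length (span 0.5, 9738 genes) was added after the data were seen, as were the alternatives to the fit with the set term. GC content and length were those of a reference transcript of the symbol, not of the amplicon. Voom on recovered reads called 0 genes without the set term and 890 with it.

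The tests were tried on simulated data in which 200 of the 10006 genes were changed. Without the set term 0 of 67 genes changed 1.5-fold, 12 of 67 changed 2-fold and 61 of 66 changed 4-fold were recovered, with 2 false calls. With the set term 1, 5 and 54 were recovered, with 4 false calls. The simulated noise was independent between genes and held no set effect. These counts therefore do not give the error rates or the power of either fit on the real libraries. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.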

Results

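Cells carrying CD11b, an integrin subunit found on microglia and other myeloid cells, were selected with magnetic beads from the brains of perfused mice of 2 genotypes. The control mice (CT, n = 3) had both Rac1 alleles floxed. The Rac1 cKO mice (n = 3) also had CreER, a hormone-dependent form of the Cre recombinase, at Cx3cr1, a gene that microglia use strongly. Here n counts libraries: whether each came from 1 mouse or a pool, and whether tamoxifen was given to either genotype, is not given in the sources used here. The RNA was read with a targeted amplicon panel, and each library gave a log2(RPM + 1) value (RPM, reads per 1000000) for 23930 gene symbols. The CT libraries held 20288428, 15341491 and 17873436 reads, and the Rac1 cKO libraries held 20509250, 14336964 and 17871314. Cst3, which encodes the protease inhibitor cystatin C, was the most abundant transcript in all 6 libraries, at 4.15% to 5.90% of the reads. The libraries carried barcodes from 2 separate ranges, which are called set 1 (CT 1, Rac1 cKO 1 and Rac1 cKO 2) and set 2 (CT 2, CT 3 and Rac1 cKO 3) from here on. Both genotypes were present in each set, so values are given without the set, with the set as a block, and within each set. Rac1 cKO 3 lay apart from the other libraries on the first principal component (47.5% of the variance), at a score of 44.1 against a range of -28.4 (CT 1) to 4.01.

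The series asks what loss of Rac1, a small GTPase that steers the actin cytoskeleton, does to microglia. The transcript of the floxed gene itself was not analysed here, so the genotypes were checked at Cx3cr1, the fractalkine receptor gene that holds the driver. Cx3cr1 stood at 10.13 ± 0.20 in CT (SD, n = 3) and 8.73 ± 0.59 in Rac1 cKO (SD, n = 3) on the log2(RPM + 1) scale. The CT libraries read 10.36, 10.01 and 10.02, and every Rac1 cKO library was lower, at 8.86, 9.25 and 8.09. The log2 difference was -1.40 (SE 0.28), a level 0.380 times that of CT. Over all genes Cx3cr1 did not pass (limma, Benjamini-Hochberg adjusted p = 0.0964), and it fell when adjusted over the list alone of homeostatic microglial genes (limma, adjusted p = 0.00815). In the fit with the set as a block it fell over all genes too, with a log2 difference of -1.61 (SE 0.20, limma, adjusted p = 0.00198), and the difference was -1.30 within set 1 and -1.92 within set 2. Over the alternatives to the fit without the set, the adjusted p of Cx3cr1 ran from 0.00109 (limma with array quality weights) to 0.436 (equal-variance test). It was 0.0287 when Rac1 cKO 2 was left out (limma). With the set term the range over alternatives was 4.67e-04 to 0.222, and Cx3cr1 did not pass without Rac1 cKO 3 (log2 difference -1.30, limma, adjusted p = 0.197) or with no filter on low values (adjusted p = 0.222).

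**Figure D1:**
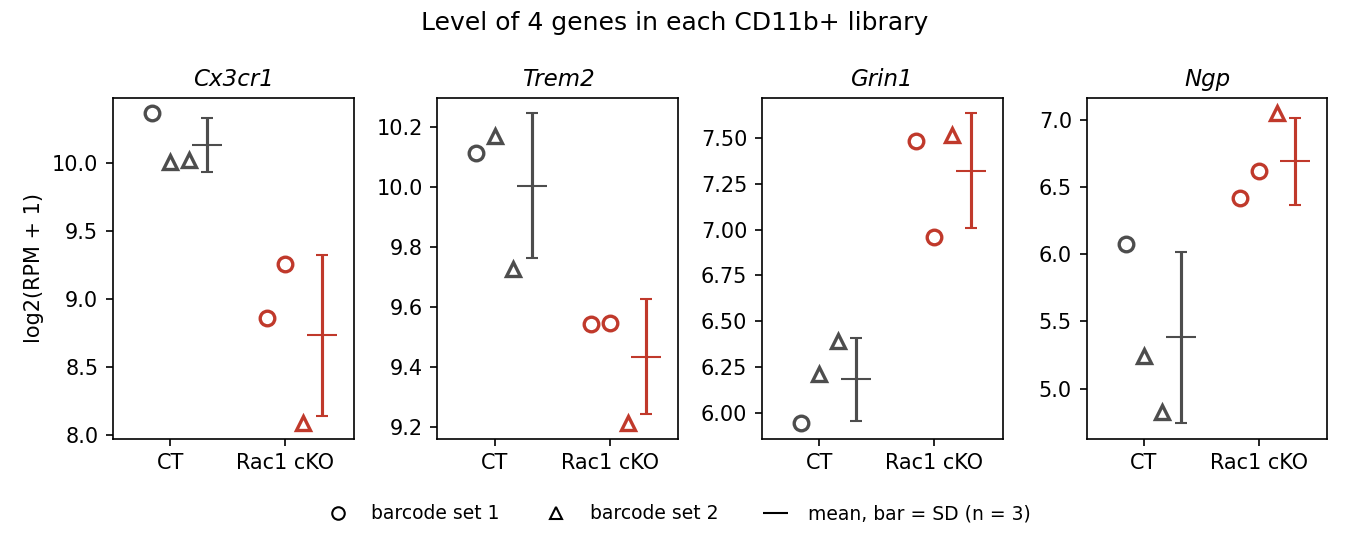
Levels on the log2(RPM + 1) scale (vertical axis) of Cx3cr1, Trem2, Grin1 and Ngp in the 3 CT and 3 Rac1 cKO libraries, with circles for set 1, triangles for set 2, and the group mean with its SD beside them. The Cx3cr1 points lie between 10.01 and 10.36 in CT and between 8.09 and 9.25 in Rac1 cKO, and the axes do not start at 0.

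Across the transcriptome, most genes that separated the genotypes were higher in Rac1 cKO. The fit without the set, the design written in advance, called 0 of 10006 genes. In the alternative fit with the set as a block 815 genes rose and 43 fell (limma, adjusted p under 0.05). These calls were lost when Rac1 cKO 3 was left out and with no filter on low values. Rac1 cKO 3 is the only Rac1 cKO library of set 2, so without it the blocked contrast rests on set 1, with 1 CT library. Of the genes that rose with non-overlapping groups, the 10 with the highest differences included matrix, guidance and cytoskeleton genes. Among them, Col6a1, a collagen VI chain, went from 6.85 ± 0.33 to 8.27 ± 0.69 (SD, n = 3 each), a log2 difference of 1.70 with the set term (SE 0.20, limma, adjusted p = 0.00198). Col4a1, a basement membrane collagen, rose by 1.62, the guidance cue Slit3 by 1.596, and the teneurin Tenm1 by 1.5997. Ryr3, a calcium release channel of the endoplasmic reticulum, rose by 1.66, Rgs11, a regulator of G protein signalling, by 1.63, and the coronin Coro6 by 1.74. Pdlim7, an actin-associated scaffold, rose by 1.65, Pip5kl1 by 1.75 and Fam135b by 1.66 (limma with the set term, adjusted p = 0.00198 to 0.00308 over these 10 genes).

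Fewer genes fell with the set term. Of the genes that fell with non-overlapping groups, the lowest after Cx3cr1 were Angptl7, a secreted angiopoietin-like protein (log2 difference -1.21, SE 0.20, limma, adjusted p = 0.00308), and Fam26f (-1.05). Tnfaip3, the A20 inhibitor of NF-kB signalling, was at -0.92, the inhibitory receptor gene Lag3 at -0.89, the DNA repair glycosylase gene Mpg at -0.88 and Fblim1, a filamin-binding protein, at -0.86. Galm, an aldose mutarotase (-0.83), Pskh1 (-0.80) and the sugar phosphate exchanger Slc37a2 (-0.79) completed the 10, with adjusted p from 0.00198 to 0.0482 in limma. Tnfaip3, Mpg and Pskh1 were at -0.46, -0.39 and -0.51 within set 1, the values with the set term when Rac1 cKO 3 was left out, and at -1.38, -1.37 and -1.09 within set 2. Adgre1, which encodes an adhesion receptor used as a macrophage marker, fell by 0.78 with the set term (SE 0.18, limma, adjusted p = 0.0175), and Dnase2a, a lysosomal nuclease, fell by 0.73 (adjusted p = 0.0361).

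Without the set term no gene passed an adjusted p of 0.05 in limma (0 of 10006, smallest adjusted p = 0.0964). At an unadjusted p under 0.05 there were 1268 genes, 1182 higher and 86 lower in Rac1 cKO, and limma's voom on recovered reads and an equal-variance test per gene called 0 genes, while array quality weights called 986 (953 higher and 33 lower). The smallest p-values among the higher genes belonged to Lrrc16b, with a log2 difference of 1.34 (SE 0.22), Mcf2l (1.15, SE 0.19), and Col4a2, the partner chain of Col4a1 (1.45, SE 0.25). They were followed by Chd5, a chromatin remodeller, at 1.13, Sptbn4, the spectrin of the axon initial segment, at 1.05, and Cacna1e, a calcium channel, at 1.41. Ltbp4, which binds latent TGF-beta, was at 1.07 and Ubap1l at 1.35. The lower genes with the smallest p-values after those named were Tnni2 (-0.65), Dclre1b (-0.66) and C1qc (-0.64), and these 3 did not pass with the set term either.

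Groups did not overlap for 1768 of the 10006 genes (17.7%, where chance gives 10%) and for 642 of the 858 genes called with the set term. The difference had the same sign in both sets for 69.7% of all genes. The 815 higher and 43 lower genes became 297 and 24 without CT 1, 917 and 83 without CT 2, 1065 and 120 without CT 3, 375 and 9 without Rac1 cKO 1, and 552 and 11 without Rac1 cKO 2. Without Rac1 cKO 3 limma called 0 genes with the set term (757 at an unadjusted p under 0.05), and with no filter on low values it called 1. Without Rac1 cKO 2, the fit without the set term called 287 genes, and a loess correction for GC content and transcript length changed the split with the set term to 610 higher and 237 lower.

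Neuronal and synaptic transcripts were higher in Rac1 cKO as a group. All 24 tested members of the neuron and synapse list had higher means, and 11 rose when adjusted over the list alone in limma, while 10 rose over all genes with the set term. Grin1, the obligate NMDA receptor subunit, went from 6.18 ± 0.23 to 7.32 ± 0.31 (SD, n = 3 each; log2 difference 1.14, SE 0.22, limma, adjusted p = 0.00483 over the list alone), and Grin2b rose by 1.19 (SE 0.29, limma, adjusted p = 0.0145 over the list alone). The abundant imprinted RNA Meg3 rose by 1.06 (SE 0.33, limma, adjusted p = 0.0261 over the list alone), from 12.40 ± 0.45. Camk2a, the kinase subunit abundant in forebrain neurons, was at 9.27 ± 0.43 and 9.69 ± 0.72 and did not pass (limma, adjusted p = 0.291 over the list alone). The median log2 difference of the list was 0.48 (limma camera, adjusted p = 2.06e-08 with a preset correlation of 0.01; adjusted p = 0.317 with an estimated correlation). It was 0.49 with the set as a block (camera, adjusted p = 9.98e-08; adjusted p = 0.267 with an estimated correlation), 0.48 within set 1 and 0.47 within set 2.

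Neutrophil genes formed the list with the highest median. Of 10 tested members 9 rose when adjusted over the list alone in limma, and 7 rose over all genes with the set term. Ngp, a neutrophil granule protein, went from 5.38 ± 0.64 to 6.69 ± 0.32 (SD, n = 3 each; log2 difference 1.31, SE 0.30, limma, adjusted p = 0.00353 over the list alone). Mmp9, a gelatinase of neutrophil granules, rose by 1.13 and S100a9, a calprotectin subunit, rose by 1.02 (limma, adjusted p = 0.00353 and 0.00995 over the list alone). The exception was Csf3r, the G-CSF receptor gene, at a log2 difference of -0.11 (SE 0.31). The list median was 1.07 (camera, adjusted p = 2.67e-07; adjusted p = 0.317 with an estimated correlation). With the set as a block it was 1.13 (camera, adjusted p = 2.01e-05; adjusted p = 0.341 with an estimated correlation), and it was 0.47 within set 1 and 1.89 within set 2. With array quality weights it was 0.67 (adjusted p = 0.00121).

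**Figure D2:**
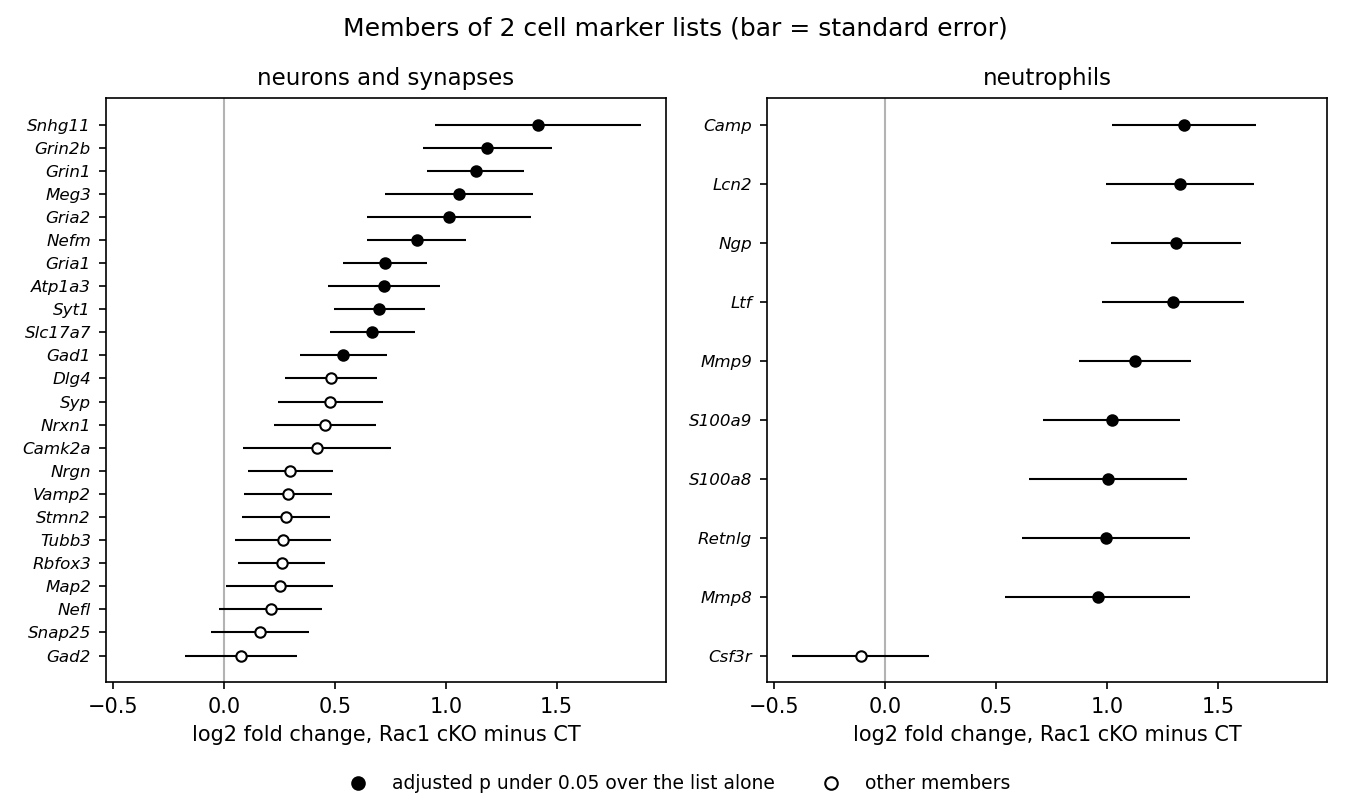
Log2 difference of Rac1 cKO against CT (horizontal axis, 3 libraries each) for each tested member of the neuron and synapse list and of the neutrophil list, with the standard error as a bar and filled points for an adjusted p under 0.05 over the list alone. All 24 neuronal members and 9 of the 10 neutrophil members lie above 0.

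Homeostatic microglial genes had lower means in Rac1 cKO by small amounts. None of the 29 tested homeostatic genes had a higher mean, and the median log2 difference was -0.22, although Cx3cr1 alone fell when adjusted over the list alone. Trem2, a lipid-sensing receptor, stood at 10.003 ± 0.24 in CT and 9.44 ± 0.19 in Rac1 cKO (SD, n = 3 each), and the abundant Cst3 at 15.79 ± 0.057 and 15.50 ± 0.22. The list was called by camera (adjusted p = 3.67e-06; adjusted p = 0.687 with an estimated correlation). With the set as a block the median was -0.38 (camera, adjusted p = 4.10e-08; adjusted p = 0.267 with an estimated correlation), and 4 members fell over the list alone, among them Trem2 and the efferocytosis receptor gene Mertk. The median was -0.20 within set 1 and -0.57 within set 2, and it was -0.05 when Rac1 cKO 3 was left out (camera, adjusted p = 0.0172) and -0.13 with array quality weights (adjusted p = 0.00121). RPM values are shares of a library's reads, and neuronal and neutrophil genes were higher in the same libraries. Rac1 cKO 3 had both the lowest median deviation of homeostatic genes from their mean over the 6 libraries (-0.55) and the highest of neutrophil genes (1.02). The homeostatic deviations were 0.27, -0.02 and 0.08 in CT, and 0.08 and 0.0008 in Rac1 cKO 1 and 2. Rac1 cKO 1 and 2 thus lay within the range of the CT libraries.

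Lysosomal and disease-associated microglial genes showed the same direction. Of 31 lysosomal genes 2 had higher means, and the median was -0.29 (camera, adjusted p = 3.77e-07; adjusted p = 0.611 with an estimated correlation). Ctsd, cathepsin D, was at 14.43 ± 0.23 and 13.99 ± 0.24, Hexa at 8.51 ± 0.12 and 7.93 ± 0.32, and Npc2, a cholesterol carrier of the lysosome, at 10.36 ± 0.32 and 9.79 ± 0.13 (SD, n = 3 each). When the set was a block the lysosomal median was -0.38 (camera, adjusted p = 4.96e-08; adjusted p = 0.267 with an estimated correlation), Hexa (-0.69) and Ctsz, cathepsin Z (-0.75), fell over all genes, and the medians within the sets were -0.30 and -0.54. For 22 disease-associated genes the median was -0.31 (camera, adjusted p = 5.58e-04; adjusted p = 0.317 with an estimated correlation), with -0.38 with the set as a block (camera, adjusted p = 2.09e-04; adjusted p = 0.267 with an estimated correlation), -0.40 within set 1 and -0.34 within set 2. Ctsl and Ctsb, further cathepsin genes of that list, had log2 differences of -0.46 (SE 0.21) and -0.39 (SE 0.28). Both are also members of the lysosome list. Of the 22 disease-associated genes 5 had higher means. Without Rac1 cKO 3 the lysosomal and disease-associated medians were -0.12 and -0.16, with array quality weights they were -0.17 and -0.19 (camera, adjusted p = 3.32e-04 and 0.00164), and without CT 1 the disease-associated median was -0.21.

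Complement, antigen presentation and NADPH oxidase genes also had negative medians. Higher means were found for 7 of 24 complement and phagocytosis genes and for 2 of 20 antigen presentation genes. For 24 complement and phagocytosis genes the median was -0.16 (camera, adjusted p = 0.00387; adjusted p = 0.739 with an estimated correlation), with C1qb at -0.48 (SE 0.25) and Itgam, the CD11b gene used for the selection, at -0.26 (SE 0.24). For 20 antigen presentation genes it was -0.24 (camera, adjusted p = 0.00136; adjusted p = 0.739 with an estimated correlation), with B2m, the class I light chain, at -0.32 (SE 0.21) and Psmb9, an immunoproteasome subunit, at -0.56 (SE 0.24). With the set as a block these medians were -0.33 and -0.38 (camera, adjusted p = 5.54e-05 and 1.65e-05; adjusted p = 0.267 for both with an estimated correlation), and the class I genes H2-D1 (-0.64) and H2-Q4 (-0.73) fell over all genes. Within sets 1 and 2 they were -0.22 and -0.42 for complement and -0.31 and -0.51 for antigen presentation, and without Rac1 cKO 3 both medians were 0.02 (adjusted p = 0.493 and 0.126). Without CT 1 they were -0.15 and -0.06 (adjusted p = 0.0924 and 0.0506), and without Rac1 cKO 1 they were -0.27 and -0.37. Without Rac1 cKO 2 the complement median was -0.29. All 6 tested NADPH oxidase genes, whose enzyme Rac proteins activate, had lower means, with Hvcn1, the proton channel gene, at -0.42 (SE 0.20) and Cyba at -0.42 (SE 0.21). Their median was -0.31 (camera, adjusted p = 0.0107; adjusted p = 0.734 with an estimated correlation), -0.41 with the set as a block (camera, adjusted p = 0.00301; adjusted p = 0.341 with an estimated correlation), -0.29 within set 1 and -0.58 within set 2. It was -0.19 without CT 1 and -0.11 without Rac1 cKO 3 (adjusted p = 0.0796 and 0.189). With no filter on low values the complement and NADPH oxidase medians were -0.13 and -0.089 (adjusted p = 0.0521 for both), and with array quality weights they were -0.069 and -0.20 (adjusted p = 0.0781 and 0.131). With these weights the antigen presentation median was -0.14 (adjusted p = 0.0184).

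**Figure D3:**
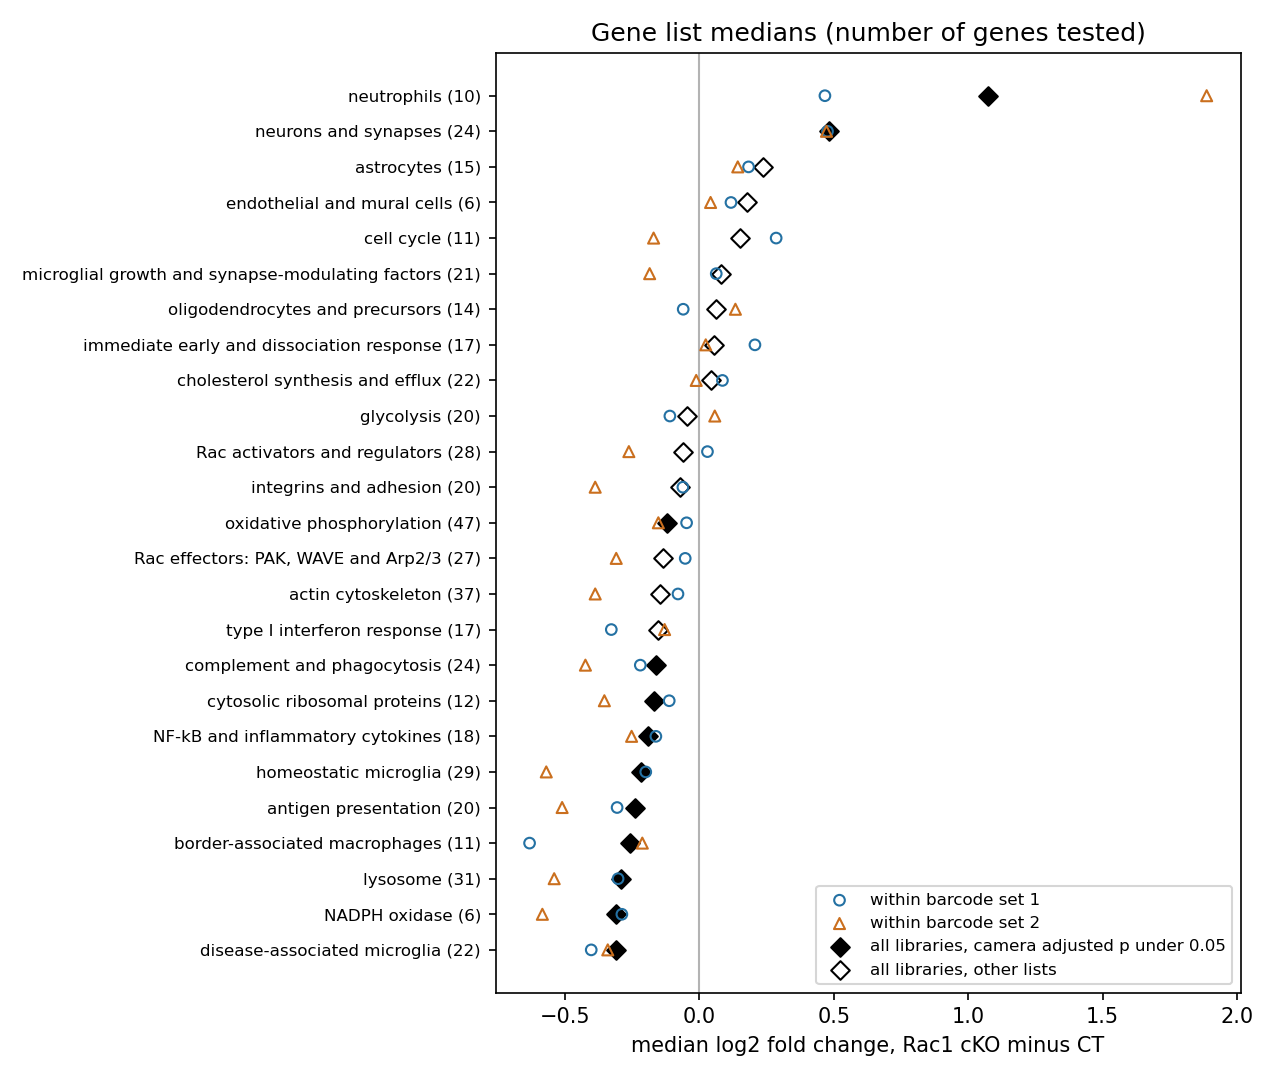
Median log2 difference of Rac1 cKO against CT (horizontal axis) for 25 of the tested lists, with diamonds for all 6 libraries (filled where camera's adjusted p with the preset correlation was under 0.05), circles for set 1 and triangles for set 2. The medians over all libraries run from -0.31 for the disease-associated list to 1.07 for the neutrophil list.

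Neither list of Rac regulators and effectors was called, although a few single members rose with the set term. The medians were -0.06 for 28 activators and regulators and -0.13 for 27 effectors (camera, adjusted p = 0.566 and 0.372). Among exchange factors, Farp1 rose by 0.77 and Tiam1 by 0.75 with the set term (limma, adjusted p = 0.0123 and 0.0186), and among effectors Baiap2 rose by 1.49 and Cyfip2 by 0.69 (adjusted p = 0.00282 and 0.0293). Neuronal transcripts were also higher in the Rac1 cKO libraries, and which cells these single members came from was not tested. Cyfip1, of the WAVE complex, was at -0.20 (SE 0.26). When the set was a block the 2 medians were -0.13 and -0.19 (camera, adjusted p = 0.220 and 0.260), within set 1 they were 0.03 and -0.05, and within set 2 they were -0.26 and -0.31.

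Neither actin nor adhesion genes were called as a list in the fit without the set. The median was -0.14 for 37 actin cytoskeleton genes (camera, adjusted p = 0.0601) and -0.07 for 20 integrins and adhesion genes (adjusted p = 0.395). Actb, cytoplasmic actin, was at 13.25 ± 0.36 in CT and 13.11 ± 0.38 in Rac1 cKO (SD, n = 3 each). Blocked by set, the actin list was called at a median of -0.26 (camera, adjusted p = 0.00301; adjusted p = 0.645 with an estimated correlation), although its member Actn1, an actin crosslinker, rose by 0.98 over all genes (SE 0.19, limma, adjusted p = 0.00604). The adhesion list was not called (median -0.22, camera, adjusted p = 0.0715), and its member Fermt2, kindlin-2, rose by 0.78 (SE 0.20, limma, adjusted p = 0.0229). Medians within sets 1 and 2 were -0.08 and -0.39 for actin and -0.06 and -0.39 for adhesion. In the fit without the set the actin list was called when CT 2, Rac1 cKO 1 or Rac1 cKO 2 was left out (medians -0.18, -0.19 and -0.19), and its median was 0.09 without Rac1 cKO 3. It was also called after the GC and length correction (median -0.19, adjusted p = 0.0150).

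Inflammatory genes had small negative medians. Higher means were found for 5 of 18 NF-kB and cytokine genes and for 4 of 17 interferon response genes. For 18 NF-kB and cytokine genes the median was -0.19 (camera, adjusted p = 0.00387; adjusted p = 0.317 with an estimated correlation), and Tnfaip3 and Nfkb2 were at -0.79 (SE 0.29) and -0.53 (SE 0.24). When the set was a block that median was -0.19 (camera, adjusted p = 0.00977; adjusted p = 0.267 with an estimated correlation), and within the sets it was -0.16 and -0.25. Without Rac1 cKO 2 and without the set term it was -0.11. For 17 interferon response genes it was -0.15 (adjusted p = 0.236), with Ifih1 at -0.47 (SE 0.38) and Stat2 at 0.56 (SE 0.23). With the set as a block it was -0.25 (camera, adjusted p = 0.0275; adjusted p = 0.617 with an estimated correlation), with -0.33 within set 1 and -0.13 within set 2. Without Rac1 cKO 1 and without the set term the interferon list was called as well, at -0.21 (adjusted p = 0.0119).

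Single genes rose in lists that were not called as a whole. Among growth and synapse-modulating factors Vegfa rose by 1.06 (SE 0.27), Cx3cl1, the ligand of the Cx3cr1 receptor, by 0.86 (SE 0.24) and Mmp9 by 1.13 (SE 0.25), each adjusted over the list alone in limma (adjusted p = 0.0212, 0.0222 and 0.0158). The median of that list was 0.08 over 21 genes (camera, adjusted p = 0.895), and Tgfb1 was at -0.41 (SE 0.25). Mmp9 is also a member of the neutrophil list, and which cells these transcripts came from was not tested. The immediate early genes Fos and Nr4a1 rose by 0.90 (SE 0.24) and 0.86 (SE 0.25) when adjusted over the list alone (limma, adjusted p = 0.0412 for both), in a list of 17 genes with a median of 0.06 (camera, adjusted p = 0.653). Pfkp, a phosphofructokinase, rose by 0.94 (SE 0.21, limma, adjusted p = 0.0122 over the list alone) among 20 glycolysis genes with a median of -0.05 (camera, adjusted p = 0.779). Srebf2, a regulator of sterol synthesis, rose by 0.75 and the cholesterol exporter gene Abca1 fell by 0.68 over all genes with the set term (limma, adjusted p = 0.0168 and 0.0376), in a list of 22 genes with a median of 0.04 (camera, adjusted p = 0.870). In the fit with the set as a block the 4 medians were -0.08, 0.11, -0.10 and 0.01, within set 1 they were 0.06, 0.21, -0.11 and 0.09, and within set 2 they were -0.19, 0.02, 0.06 and -0.01.

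Lists of housekeeping genes had small negative medians. Higher means were found for 10 of 47 oxidative phosphorylation genes and for 0 of 12 cytosolic ribosomal protein genes. The median was -0.12 for 47 oxidative phosphorylation genes (camera, adjusted p = 0.00629; adjusted p = 0.781 with an estimated correlation), with Cox6a1 at 0.12 (SE 0.24) and Ndufa1 at -0.25 (SE 0.19). It was -0.17 for 12 cytosolic ribosomal protein genes (adjusted p = 0.00612; adjusted p = 0.739 with an estimated correlation), with Rps15 at -0.14 (SE 0.23) and Rpl30 at -0.41 (SE 0.23). In the blocked fit these medians were -0.09 and -0.22 (camera, adjusted p = 0.0161 and 0.0202; adjusted p = 0.834 and 0.711 with an estimated correlation), with -0.05 and -0.15 within the sets for oxidative phosphorylation and -0.11 and -0.35 for ribosomal proteins. Without CT 2 the 2 medians were 0.03 and -0.03 (adjusted p = 0.479 and 0.294), and without CT 3 they were -0.20 and -0.32. Without Rac1 cKO 1 or Rac1 cKO 3 the oxidative phosphorylation median was -0.07. Neither list was called with quantile normalization (medians -0.13 and -0.14, adjusted p = 0.10003 and 0.185) or after the GC and length correction (-0.061 and -0.16, adjusted p = 0.524 and 0.0647). For 11 cell cycle genes the median was 0.15 (adjusted p = 0.653) and 0.03 with the set as a block, with Birc5, survivin, rising by 0.99 and Mcm3, a replication helicase subunit, falling by 0.86 over all genes with the set term (limma, adjusted p = 0.0208 and 0.0231), and with medians of 0.29 and -0.17 within the sets. With 1 library left out the cell cycle median ran from 0.01 (CT 2) to 0.31 (Rac1 cKO 3).

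Of the other tested cell types, border-associated macrophages had the lowest median and astrocytes the highest over all 6 libraries. The astrocyte rank did not hold in every setting. Endothelial and mural genes had the higher median with array quality weights (0.15 against -0.03) and without CT 3 or Rac1 cKO 2. For 11 border-associated macrophage genes the median was -0.26 (camera, adjusted p = 0.00612; adjusted p = 0.739 with an estimated correlation), with Stab1 at -0.26 (SE 0.28) and Cd209f at -0.59 (SE 0.27), and it was -0.45 with the set as a block (camera, adjusted p = 6.79e-04; adjusted p = 0.362 with an estimated correlation), -0.63 within set 1 and -0.21 within set 2. It was -0.01 without CT 1 and -0.28 without Rac1 cKO 2 (adjusted p = 0.398 and 0.104), and -0.43 without CT 2 and -0.40 without Rac1 cKO 1. The median was 0.24 for 15 astrocyte genes, 0.06 for 14 oligodendrocyte lineage genes and 0.18 for 6 endothelial and mural genes (camera, adjusted p = 0.121, 0.653 and 0.653). The astrocyte list was called at 0.39 without Rac1 cKO 1 and at 0.26 without Rac1 cKO 3 (adjusted p = 0.0156 and 0.0322), and at 0.20 with quantile normalization (adjusted p = 0.0232). It was not called at 0.06 without CT 3 or at 0.04 without Rac1 cKO 2 (adjusted p = 0.450 and 0.953), nor over all libraries with an estimated correlation (adjusted p = 0.781). The endothelial median was 0.09 without Rac1 cKO 1 and 0.02 with quantile normalization. The glutamate transporter gene Slc1a2 of astrocytes was at 0.24 (SE 0.26) and Gfap at 0.59 (SE 0.24), while the myelin gene Mbp was at -0.06 (SE 0.27) and the oligodendrocyte factor Sox10 rose by 0.81 over all genes with the set term (SE 0.22, limma, adjusted p = 0.0356). In the fit with the set as a block these 3 medians were 0.19, -0.07 and 0.12, within set 1 they were 0.18, -0.06 and 0.12, and within set 2 they were 0.14, 0.13 and 0.04. Monocyte, lymphocyte, erythroid and ependymal lists had 2, 1, 1 and 2 members above the filter and were not tested, with medians of 0.38, -0.08, -0.03 and -0.15.

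Over the 26 tested lists camera called 12 with the preset correlation, 2 higher and 10 lower, and 14 with the set as a block, 2 higher and 12 lower. Without the set, other splits of the 6 libraries into 3 and 3 also gave calls, from 5 to 15 lists. No list was called with an estimated correlation (0 of 26, smallest adjusted p = 0.317, or 0.267 with the set as a block). The rotation test fry asks whether the members of a list move one way and does not compare them with other genes. It called 0 lists (fry, smallest adjusted p = 0.0661). With the set as a block it called 2, neurons and synapses and disease-associated microglia (fry, adjusted p = 0.0143 for both). Its form for members that move either way called 1 list without the set, neurons and synapses (fry, adjusted p = 0.0263).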

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

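The correction for GC content and length and the tests that vary the fit with the set term were chosen after the result was seen, and the others, the barcode set included, before. The number of genes passing without the set term was 0 (limma, 1268 at an unadjusted p under 0.05). It was 1 without a filter, 986 with array quality weights, 858 with the barcode set, 241 at an unadjusted p under 0.05 with at least a 2-fold difference, 109 at an adjusted p under 0.10, and 0 to 287 when 1 library was left out (287 without Rac1 cKO 2). The weights gave Rac1 cKO 1 6.06 and Rac1 cKO 3 0.325. With the set term the count of 858 became 1 without a filter, 476 with the stricter filter (all 476 shared), 575 with quantile normalization (555 shared) and 847 after the GC and length correction (619 shared, 610 higher and 237 lower). Leaving out 1 library with the set term gave 0 (Rac1 cKO 3), 321 (CT 1), 384 (Rac1 cKO 1), 563 (Rac1 cKO 2), 1000 (CT 2) and 1185 (CT 3). Cx3cr1 was at -1.35 with array quality weights, -1.61 with the barcode set, and -1.66 to -1.07 with 1 library left out. Called lists numbered 12, and 1 with a median of at least 2-fold, 0 with an estimated correlation, 0 with fry, 14 with the barcode set and 8 to 15 with 1 library left out. The cause of these dependences was not tested.

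A replicate block changed no call: 0 genes (1317 at an unadjusted p under 0.05), Cx3cr1 at -1.40 (adjusted p = 0.0636, over alternatives 0.00109 to 0.436) and 12 lists. Libraries with the same number had deviations correlated at 0.45, -0.17 and 0.09, and not every library correlated best with its own number. These values do not show a pairing by number and cannot exclude one. Most pairs followed the sets, but not all. Within a set the values were 0.45 and 0.51 for CT 1 with Rac1 cKO 1 and 2. They were 0.45 and 0.09 for CT 2 and CT 3 with Rac1 cKO 3. Across sets CT 1 was at -0.65 with Rac1 cKO 3. CT 2 was at -0.54 with Rac1 cKO 1 and at -0.17 with Rac1 cKO 2. CT 3 was at 0.18 with Rac1 cKO 1 and at -0.26 with Rac1 cKO 2. It thus correlated better with Rac1 cKO 1 than with the Rac1 cKO library of its own set.

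Some list medians changed sign. With 1 library left out the ranges were -0.17 to 0.084 for Rac regulators, -0.21 to 0.020 for effectors, -0.19 to 0.092 for actin, -0.20 to 0.11 for adhesion, -0.29 to 0.022 for complement, -0.21 to 0.052 for interferon response, -0.37 to 0.019 for antigen presentation, -0.064 to 0.17 for growth factors, -0.049 to 0.25 for immediate early genes, -0.071 to 0.10 for glycolysis, -0.20 to 0.032 for oxidative phosphorylation, -0.050 to 0.13 for cholesterol and -0.088 to 0.24 for oligodendrocytes. The ranges were 0.0091 to 0.31 for cell cycle, 0.041 to 0.39 for astrocytes and 0.089 to 0.23 for endothelial genes, without a change of sign. The stricter filter gave -0.086 for growth factors, -0.0010 for immediate early genes and -0.030 for oligodendrocytes. Quantile normalization gave -0.048 for growth factors, -0.014 for immediate early genes and -0.026 for cholesterol. Median centring gave -0.024 for immediate early genes, -0.037 for cholesterol and -0.018 for oligodendrocytes. Array quality weights gave 0.082 for adhesion, -0.026 for cholesterol, -0.026 for astrocytes and -0.034 for oligodendrocytes. The barcode set gave -0.083 for growth factors and -0.073 for oligodendrocytes. The GC and length correction gave -0.0047 for growth factors, -0.011 for immediate early genes and -0.0022 for oligodendrocytes. Outside the leave-one-out settings, medians that stayed called but moved by a factor over 1.5 were, with array quality weights, -0.13 for homeostatic, -0.17 for lysosomal, -0.19 for disease-associated, -0.14 for antigen presentation and 0.67 for neutrophil genes. They were also -0.26 for complement with the stricter filter and -0.25 after the GC and length correction, -0.12 and -0.13 for NF-kB genes without a filter and after that correction, and -0.20 for oxidative phosphorylation with median centring. With the barcode set they were -0.38 for homeostatic and for antigen presentation, -0.33 for complement and -0.45 for border-associated macrophage genes. In these settings 8 values of called lists lost their call and 4 values of lists not called gained one. In the fit without the set term 0 genes passed, so no named gene had a call to lose. Over the same alternatives 54 values of the named genes gained one and none changed sign. The rule took genes with non-overlapping groups, and some because they passed with the set term, so these counts follow in part from the choice.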

Other observations

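All tests in this part were chosen after the result was seen, except the count of other splits for the gene lists. The families of genes below were picked after the genes with the highest differences had been seen, so their counts describe and test nothing, and they rest on calls with the set term that number 0 without Rac1 cKO 3. Of 20 glutamate receptor genes 13 rose with the set term, where 8.15% of all tested genes rose. Grm7, a metabotropic receptor, rose by 1.55 with the set term, the NMDA receptor gene Grin2a by 1.55 and the kainate receptor gene Grik3 by 1.46. Of 13 collagen chain genes 9 rose, among them Col11a1 at 1.64 and Col23a1 at 1.49. The counts were 10 of 19 for voltage-gated calcium channels, 9 of 22 for potassium channels, 4 of 13 for Eph receptors and ephrins, 8 of 198 for zinc finger genes of the Zfp series, 0 of 62 for mitochondrial ribosomal proteins, 0 of 34 for the proteasome and 0 of 5 for the replication helicase. Olfactory and vomeronasal receptor genes summed to 182.0, 550.4 and 169.8 RPM in CT and 238.8, 295.4 and 488.5 RPM in Rac1 cKO.

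The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 0 genes and the highest other 1, so all 10 gave as many. At an unadjusted p under 0.05 the real split gave 1268 genes, and 1 split gave as many, itself. The highest other, 1139, was the split that follows the barcode set, and with the set as a block the real split gave 858 genes and the highest of the other 8 gave 0, so 1 of 9 gave as many. For the lists the real split gave 12 and the highest other 15, and 2 splits gave as many. Every other split called at least 5 lists, so a camera call with the preset correlation was not particular to the genotypes.

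Neuronal transcripts were higher in Rac1 cKO. A bias by GC content or length of the whole transcript is argued against as the only cause. The median of the list was 0.36 after the correction and 0.48 before. A contribution is not excluded, since the log2 difference of the tested genes correlated with both. The Spearman correlation was 0.21 with GC content and 0.20 with length, and 0.08 and 0.16 with the set term. The correction did not use the amplicons, so a bias by amplicon GC content was not tested. Whole neuronal RNA carried into the selection and a larger share of neuronal nuclear RNA cannot be told apart. Nuclear long non-coding RNAs had a median of 0.62 and abundant cytoplasmic neuronal mRNAs one of 0.27, but the difference of the means was 0.35 (SE 0.34) and the libraries overlapped. With the set as a block the medians were 0.73 and 0.30, and within each set they were 0.80 and 0.29. The nuclear minus cytoplasmic value was -0.43 in CT and 0.43 and -0.40 in Rac1 cKO in set 1. In set 2 it was -0.27 and 0.18 in CT and 0.49 in Rac1 cKO. Miat (1.43) and Firre (0.95) were among the higher nuclear RNAs, with Malat1 at -0.05, and Snap25 was at 0.16, so either source may contribute, and a change in the microglia was not tested.

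Neutrophil genes were higher in Rac1 cKO. More neutrophil RNA in the selection may explain this, since CD11b is also on neutrophils, but it stays open: 9 of the 10 detected neutrophil genes were higher in both sets, a count that restates the pattern and does not separate this cause from others. A GC or length bias of the whole transcript is argued against by a corrected median of 1.06 against 1.07, while a bias by amplicon was not tested. A difference in depth is argued against by a ratio of mean totals of 0.985 with overlapping totals. Whether such cells came from tissue or from blood left in the vessels was not tested.

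Cx3cr1 was lower in Rac1 cKO. The difference of -1.40 has an interval that includes -1, the value for loss of 1 of 2 alleles to CreER, while the interval with the set term, -2.05 to -1.18, excludes it, so this explanation stays open. A general fall of homeostatic transcripts is argued against as the cause, since the other members had a median of -0.21 and all 28 lay above the interval of Cx3cr1. Loss of the Rac1 protein may add to the fall, which was not tested.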
